A study of Mus musculus with 4 samples.

How the data were processed

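RNA was measured in 4 mouse lung cancer cell lines, each with 1 library. All came from 129S1/SvImJ mice whose tumours were started by Cre recombinase, which deletes their floxed p53 (Trp53) alleles. The growth notes describe cultured cancer cells, while the treatment notes call the samples tumours, and they are treated here as cultured lines. The lines 238N1 and 482N1 were labelled metastatic and came from lymph nodes. The lines 368T1 and 394T4 were labelled non-metastatic and came from the lung. Per the labels and the series design text, total RNA from cultured cells was made into Illumina TruSeq libraries and sequenced as paired reads of 100 bp. Reads were aligned to mm9, and TopHat is named in the submitters' processing notes with no version. The tool that turned alignments into gene values and its annotation are not given in the sources used here. The deposited values are FPKM (fragments scaled to transcript length and to sequencing depth), per the file headers, in 1 column per line, and no scaling between libraries is stated.

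The table held 37527 rows with 34147 distinct symbols, and where rows shared a symbol the row with the highest mean FPKM was used. Positions were taken from GENCODE vM1 on NCBIM37, the same assembly as mm9, which held the gene IDs of 99.0% of the rows. Read totals are unknown. The smallest FPKM values step in units of 1 fragment, however, so the commonest ratio of values below a mean of 0.08 FPKM gave the libraries' relative depth. By that measure 238N1 was the deepest, and 482N1, 368T1 and 394T4 had 0.58, 0.61 and 0.55 of its depth, with 162 of 937, 130 of 744 and 122 of 742 genes within 1% of the commonest ratio. This assumes the same normalisation in each library. No counts were recovered for genes in general, so no counting intervals or detection limits are given. A value of exactly 0 was also found in genes that growing cells use: 313 rows were at 0 in at least 1 library with at least 20 FPKM in another, out of 5611 rows that reached 20 FPKM anywhere. Such a gene is described only as listed at 0, with each library's value.

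The test was limma with a variance trend on log2(FPKM + 1), for the 12425 genes with a mean FPKM of at least 1 over the 4 libraries, with all 4 libraries in the fit, no covariate, two-sided, and Benjamini-Hochberg adjusted p under 0.05. Fold changes are differences on the log2(FPKM + 1) scale, metastatic minus non-metastatic, with their standard errors (SE), and this scale understates the change of genes with low values. There were 29 gene lists. Lists with at least 3 tested members were tested two-sided with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists tested. Each test was repeated with an estimated correlation, and with fry. With an estimated correlation, camera is limited to the residual degrees of freedom, of which 4 libraries leave few. A call lost in that fit therefore cannot tell whether correlation among members accounts for a list. The estimates, though imprecise, differed between the called lists. They were 0.595 for mesenchymal, 0.563 for TGF-beta and BMP pathway, 0.365 for epithelial and 0.273 for hypoxia and glycolysis genes. For these lists camera's p at the preset 0.01 may be too small. The other called lists had slightly negative estimates. Counts of members past the gene test were also adjusted over the list alone. For each list, the median fold change was placed among 10000 random lists matched on mean expression. Similarity was described by Spearman correlation across genes for the 6 pairs of lines and by the number of genes over 4-fold apart. Here 4-fold refers to FPKM + 1, so genes with low values can differ more in FPKM without being counted.

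The tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named the 12 largest rises and the 12 largest falls past the test among genes whose groups did not overlap, whose higher group averaged at least 5 FPKM and whose symbol was no clone or model name. Places left were filled from genes with an unadjusted p under 0.05. Of each list it named up to 4 members past the test, or the 2 with the largest fold change where none passed. It always named Trp53, Nkx2-1, Hmga2, Cd109, Cdh1, Epcam and Vim. Some genes under this rule are not reported here. Within each group, it named the 8 genes of at least 10 FPKM that differed most between the 2 lines. Alternatives were another pseudocount (0.1 or 5), no filter or a mean FPKM of at least 5, quantile normalization, scaling to the library sum, median centring, limma without the trend or with robust=TRUE, each library left out in turn, a 2-fold minimum, limma's treat against a fold of 1.5, and rows of a symbol added up. Chosen after seeing the data were the removal of genes listed at 0 in any library (11454 genes left), exact 0 as a missing value, protein-coding genes alone, and scaling to the sum of protein-coding genes.

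The scripts were tested on simulated data for this comparison with 11321 genes, 200 of them changed. The simulated genes were independent and modelled on genes above 0 in every library, so none stood for the 971 tested genes listed at 0. All 20 calls of the main test were genes listed at 0, so the recovery below does not measure that test's power. Of 50 genes changed 2-fold, 2 were called, of 50 changed 4-fold, 38, of 50 changed 16-fold, 49, and of 50 changed 64-fold, 48; 7 unchanged genes were called. With 2 lines per group there are 3 ways to split the 4 lines into pairs, so an exact permutation test cannot give a p under 0.33. Each line is a single library, nothing says that cultures were replicated, and p-values therefore measure only the spread between these lines. Metastatic status and the site of origin coincide and cannot be separated. R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, were used.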

Results

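Gene expression was compared between 2 metastatic mouse lung cancer lines from lymph nodes, 238N1 and 482N1, and 2 non-metastatic lines from the lung, 368T1 and 394T4. Each line was sequenced once. The FPKM values of the libraries summed to 924354 in 238N1, 1215661 in 482N1, 2279794 in 368T1 and 1197605 in 394T4. A single row, AC113316.1, took 18.7%, 45.4%, 62.4% and 32.5% of these sums. Summed over protein-coding genes, the libraries were closer, at 418847, 412799, 491717 and 477102. By the worth of 1 fragment, 238N1 was sequenced about 1.72 times as deeply as 482N1, 1.64 times as deeply as 368T1 and 1.82 times as deeply as 394T4, if the values of all libraries were normalised in the same way.

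Trp53 (chromosome 11, 69393861 to 69405375, mm9), which encodes the tumour suppressor p53 and whose alleles were built to be deleted in all 4 lines, stood at 1.57 FPKM in 238N1 and 2.74 in 394T4 and was listed at 0 in 482N1 and 368T1 (adjusted p = 0.881).

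The first question was which genes distinguish the metastatic from the non-metastatic lines. Several epithelial genes, all above 0 in every library, stood far lower in the metastatic lines. Epcam, an epithelial cell adhesion molecule, averaged 4.44 ± 0.445 FPKM in the metastatic and 44.1 ± 13.9 FPKM in the non-metastatic lines (mean ± SD, n = 2 each; log2 fold change -3.02, SE 0.28). Cldn4, a tight junction claudin, averaged 10.96 ± 3.46 against 128.3 ± 5.15 FPKM (-3.47, SE 0.25). St14, a membrane serine protease of epithelia, averaged 0.676 ± 0.272 against 24.9 ± 8.15 FPKM (-3.92, SE 0.33), and Sfn, the epithelial 14-3-3 protein stratifin, 1.21 ± 0.905 against 52.7 ± 10.2 FPKM (-4.65, SE 0.37). None of these genes passed over all 12425 genes, with adjusted p = 0.0997 for Epcam, 0.0596 for Cldn4, 0.0786 for St14 and 0.0743 for Sfn.

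Those genes did pass when genes listed at 0 in any library were left out, an alternative chosen after the data were seen. In that fit no gene rose and 6 genes fell: Cldn4 (chromosome 5, 135420996 to 135422804; adjusted p = 0.0298), Sfn (chromosome 4, 133156471 to 133158083; 0.0298), St14 (chromosome 9, 30896987 to 30939438; 0.0315), Kcnk1 (chromosome 8, 128519002 to 128554583; 0.0315), Wnt10a (chromosome 1, 74838090 to 74850753; 0.0385) and Epcam (chromosome 17, 88035319 to 88050446; 0.0387). Kcnk1, a potassium channel subunit, stood at 0.503 and 0.334 FPKM in 238N1 and 482N1 and at 23.1 and 14.2 FPKM in 368T1 and 394T4. Wnt10a, a secreted Wnt ligand, stood at 0.161 and 0.0928 against 13.8 and 9.003 FPKM. The SE values given for these genes are from the fit to all 12425 genes.

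Over all genes tested, limma called 14 genes higher and 6 lower in the metastatic lines, and each of the 20 was listed at 0 in both lines of the other group. The higher ones included Ano1, a calcium-activated chloride channel (162.0 FPKM in 238N1 and 212.0 in 482N1; adjusted p = 0.00747), Ssrp1, a subunit of the histone chaperone FACT (148.7 and 201.8; 0.00747), Nt5dc2 (49.7 and 46.1; 0.0111), Yars, the tyrosyl-tRNA synthetase (34.1 and 44.5; 0.0171), Pomgnt1 (32.2 and 32.4; 0.0171) and Fblim1 (27.0 and 35.6; 0.0217). Top3b (28.7 and 31.2 FPKM; adjusted p = 0.0171), C77080 (29.8 and 29.7; 0.0171), Stat6 (24.6 and 27.2; 0.0191), Tsc22d4 (22.1 and 27.8; 0.0239) and Dyrk1b (18.1 and 15.5; 0.0324) followed. The lower ones included Gss, glutathione synthetase (69.2 FPKM in 368T1 and 60.8 in 394T4; adjusted p = 0.00916), Wdr55 (29.0 and 33.9; 0.0171), Aven (28.1 and 21.6; 0.0254) and Ppp1r15a (17.6 and 16.4; 0.0298). The other calls were non-coding RNAs or pseudogenes. Dividing cells use Ssrp1 and Yars, so a 0 may be a failed estimate, and no fold is given against a group at 0.

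No gene passed limma's test in either direction when any 1 library was left out. In those fits 1 line stood against 2, and its spread was taken from the other group, while Ano1 was still at 162.0 or 212.0 FPKM against 0. At an unadjusted p under 0.05 there were 1079 lower and 708 higher genes with all 4 libraries. Which direction held more genes depended on scaling. With the protein-coding sum there were 469 lower and 1497 higher genes, and with the library sum 202 and 945. Median centring gave 1250 lower and 602 higher genes. Leaving out 238N1, 482N1, 368T1 or 394T4 gave 1281, 758, 239 and 578 lower genes and 1310, 370, 299 and 585 higher genes at that threshold.

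Several further genes named by rule did not pass and are given as values. Col6a1, a chain of collagen VI, stood at 11.1 FPKM in 238N1 and 62.4 in 482N1 and was listed at 0 in both lung lines (adjusted p = 0.328). Rab25, an epithelial small GTPase, stood at 0.0455 FPKM in 238N1, 0 in 482N1, 67.1 in 368T1 and 24.7 in 394T4 (adjusted p = 0.104). Ap1m2, the epithelial adaptor subunit, was listed at 0 in both metastatic lines with 23.1 and 11.4 FPKM in 368T1 and 394T4 (adjusted p = 0.104). Il24, a secreted cytokine, stood at 0.339, 0, 27.2 and 18.5 FPKM in 238N1, 482N1, 368T1 and 394T4 (adjusted p = 0.0607). Prl, prolactin, and the non-coding rows AC152062.1 and U1 were listed at 0 in both metastatic lines, with 29.4 and 65.5, 31.6 and 128.3, and 27.5 and 11.9 FPKM in 368T1 and 394T4 (adjusted p = 0.0743, 0.151 and 0.124).

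The second question was which fixed gene lists differ as a whole, and the list of epithelial genes differed most. Camera called 8 lists for the real groups, but also 8 and 6 when the 4 lines were split in the other 2 ways, each mixing the groups. The epithelial list fell: 23 of its 26 tested members had a negative fold change, and in 21 both metastatic lines lay below both non-metastatic lines, which chance alone gives for 16.7% of genes. Lists that did not pass also exceeded that chance share. Both metastatic lines lay below in 11 of 27 endoplasmic reticulum and amino acid stress genes and above in 6 of 21 YAP and TAZ targets. The share among all genes tested is not given here. The median log2 fold change was -1.50 and camera's adjusted p was 1.6e-11. With an estimated correlation the call was lost (adjusted p = 0.539), as it was for every list called. No member passed over all genes, and 14 were lower when p was adjusted over the list alone. These 14 were Epcam, the claudins Cldn3, Cldn4 and Cldn7, Ocln, Marveld3, St14, Spint1, Prss8, Rab25, Ap1m2, Krt8 and the epithelial regulators Esrp1 and Grhl2. Cldn3 stood at 2.46 and 9.54 FPKM in the metastatic and 191.8 and 72.4 FPKM in the non-metastatic lines (log2 fold change -4.30, SE 0.75, adjusted p = 0.319). Esrp1, an epithelial splicing regulator, and Grhl2, an epithelial transcription factor, were listed at 0 in both metastatic lines, with 14.1 and 8.06 FPKM for Esrp1 and 2.57 and 2.28 FPKM for Grhl2 in 368T1 and 394T4.

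The difference was smaller or absent in other epithelial genes. Cdh1, E-cadherin, averaged 139.1 ± 49.1 FPKM in the metastatic and 131.9 ± 32.8 FPKM in the non-metastatic lines (n = 2 each; log2 fold change 0.05, SE 0.33, adjusted p = 0.942). Krt18 and Krt8 were abundant in all 4 lines and did not pass over all genes, with Krt18 at 952.5 ± 88.2 against 1340 ± 155 FPKM and Krt8 at 569.6 ± 91.7 against 879.1 ± 35.9 FPKM (n = 2 each; adjusted p = 0.340 and 0.335). Krt7 was low in 1 line, at 349.6 FPKM in 238N1, 6.90 in 482N1, 456.0 in 368T1 and 480.0 in 394T4. Esrp2, the paralog of Esrp1, averaged 17.2 ± 5.87 against 19.5 ± 4.34 FPKM (adjusted p = 0.747).

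**Figure D1:**
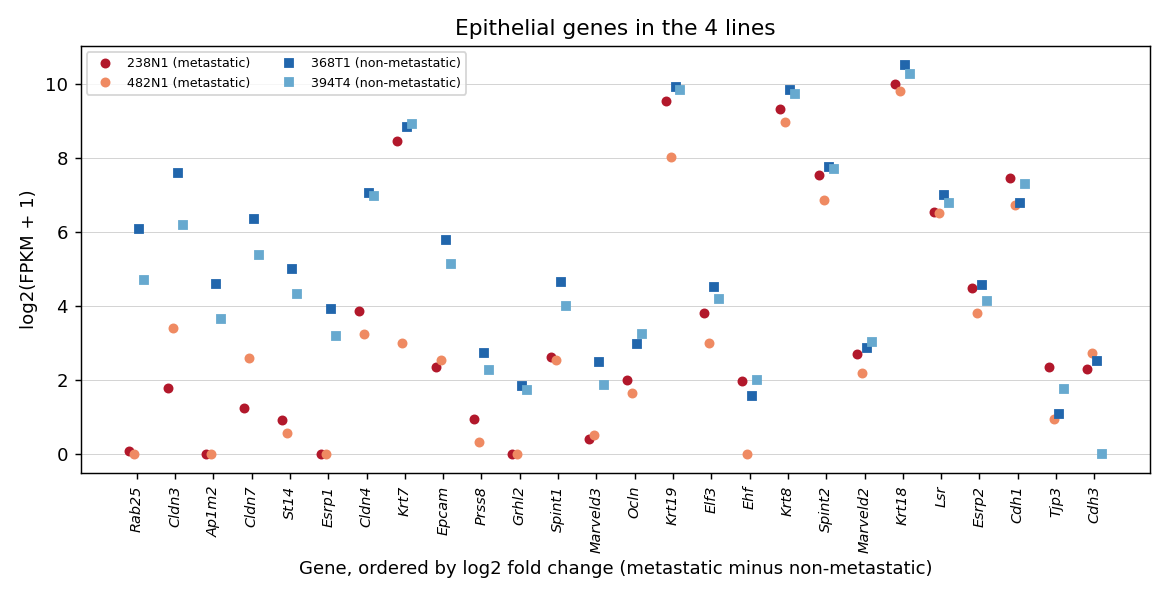
Expression of the 26 tested epithelial genes, as log2(FPKM + 1) on the vertical axis, in each of the 4 lines (circles, metastatic; squares, non-metastatic), ordered by fold change. Epcam lies at 4.13 and 4.76 FPKM in the metastatic lines and at 54.0 and 34.3 FPKM in the others, while Cdh1 overlaps between the groups.

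Mesenchymal genes were higher as a list (median log2 fold change 0.61, adjusted p = 0.00229), with a positive fold change in 21 of 22 tested members. Both metastatic lines lay above the others in 8, against 16.7% by chance, a share that lists not past the test also exceeded. The call was lost with an estimated correlation (adjusted p = 0.758) and without 482N1 (adjusted p = 0.317), the line with the most stromal markers of at least 1 FPKM. Twist1, a mesenchymal transcription factor, averaged 21.1 ± 13.1 against 2.35 ± 1.12 FPKM (n = 2 each; log2 fold change 2.63, SE 0.54, adjusted p = 0.328), and Wnt5a 11.4 ± 11.4 against 0.688 ± 0.473 FPKM (2.51, SE 0.83, 0.340). Vim, vimentin, was abundant in all 4 lines, at 1437 FPKM in 238N1, 2533 in 482N1, 1472 in 368T1 and 1438 in 394T4 (adjusted p = 0.513). No member passed over all genes or when adjusted over the list alone.

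TGF-beta and BMP pathway genes were also higher as a list (median 0.76, adjusted p = 0.00279), with a positive fold change in 25 of 28 members. Both metastatic lines lay above the others in 13, against 16.7% by chance, a share that lists not past the test also exceeded. The call was lost with an estimated correlation (adjusted p = 0.758) and without 482N1 (adjusted p = 0.424). The ligand Bmp7 stood at 10.8, 77.4, 11.05 and 1.26 FPKM in 238N1, 482N1, 368T1 and 394T4 (adjusted p = 0.387). Id2, a target of BMP signalling, averaged 90.1 ± 44.7 against 21.0 ± 5.80 FPKM (n = 2 each; log2 fold change 1.98, SE 0.43, adjusted p = 0.328), and the ligand Tgfb1 72.9 ± 20.9 against 29.6 ± 3.59 FPKM (1.25, SE 0.26, 0.328). No member passed over all genes or adjusted over the list alone.

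Alveolar type 2 and club cell genes were lower as a list (10 of 13 tested members with a negative fold change; median -0.75, adjusted p = 0.0321). The call was lost with an estimated correlation (adjusted p = 0.539), without 482N1 (adjusted p = 0.175), without 394T4 (adjusted p = 0.186) and at a mean FPKM of at least 5 (adjusted p = 0.243). Nkx2-1, the lung lineage transcription factor, stood at 0.0619 FPKM in 238N1, 0 in 482N1, 2.42 in 368T1 and 4.00 in 394T4 (adjusted p = 0.328). Cldn18, the lung and stomach claudin, stood at 9.89, 0.511, 37.4 and 54.0 FPKM (adjusted p = 0.335), and Dlk1 at 97.2 FPKM in 482N1 and 0 in the others. The surfactant gene Sftpb stood at 13.7 FPKM in 394T4 and 0.282 FPKM in 368T1, and 10 of the 23 members averaged under 1 FPKM. Of alveolar type 1 genes, Aqp5, a water channel, averaged 136.4 ± 77.8 against 26.1 ± 4.47 FPKM (n = 2 each; log2 fold change 2.23, SE 0.46, adjusted p = 0.328) and Gprc5a 158.9 ± 93.5 against 266.0 ± 40.5 FPKM (-0.87, SE 0.47, 0.405); that list did not pass (median -0.24, adjusted p = 0.404).

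Cytokine and chemokine genes were lower as a list (14 of 21 tested members; median -0.43, adjusted p = 0.0321). The call was lost with an estimated correlation (adjusted p = 0.539), without 238N1 (adjusted p = 0.207) and without 368T1 (adjusted p = 0.143). It was also lost with a pseudocount of 0.1 (adjusted p = 0.0501), with no filter (0.0889) and at a mean FPKM of at least 5 (0.104). The 3 members lower when adjusted over the list alone were Lif, at 4.66 ± 1.34 against 18.4 ± 3.79 FPKM (n = 2 each), Il23a, at 0.104, 0.0599, 5.08 and 3.98 FPKM in 238N1, 482N1, 368T1 and 394T4, and Csf3, at 0.200, 0, 3.99 and 2.48 FPKM. Cxcl16 stood at 13.7, 0, 41.8 and 29.4 FPKM (adjusted p = 0.357). Ccl9 belonged to 1 line, with 589.2 FPKM in 394T4 and at most 1.37 FPKM in the others (adjusted p = 0.438).

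Growth and energy genes were modestly lower as lists. Hypoxia and glycolysis genes fell (23 of 28 members; median -0.47, adjusted p = 0.000249; with an estimated correlation, adjusted p = 0.603), with Ndrg1 at 18.0 ± 8.71 against 43.0 ± 0.397 FPKM (n = 2 each) and Pfkfb3 at 6.55, 0, 7.15 and 11.03 FPKM in 238N1, 482N1, 368T1 and 394T4. Proliferation genes fell (26 of 36; median -0.32, adjusted p = 0.000249; with an estimated correlation, adjusted p = 0.489), with Mybl2, a cell-cycle transcription factor, at 12.8 ± 1.14 against 28.8 ± 5.15 FPKM (n = 2 each) and Ccne2 at 5.23, 8.12, 4.21 and 0 FPKM. Oxidative phosphorylation genes fell (33 of 41; median -0.32, adjusted p = 0.000216; with an estimated correlation, adjusted p = 0.489), with Cyc1 at 106.3 ± 4.01 against 215.3 ± 48.5 FPKM (n = 2 each) and Ndufs1 at 25.4, 31.2, 0 and 24.4 FPKM. No member of these 3 lists passed over all genes or adjusted over the list alone. The oxidative phosphorylation call was lost with quantile normalization (adjusted p = 0.164) and after scaling to the library sum (0.317), and the proliferation call after the latter (0.175). Among 10000 random lists of like expression, the medians lay at percentile 7.49 for oxidative phosphorylation, 1.78 for proliferation and 0.03 for hypoxia and glycolysis genes.

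**Figure D2:**
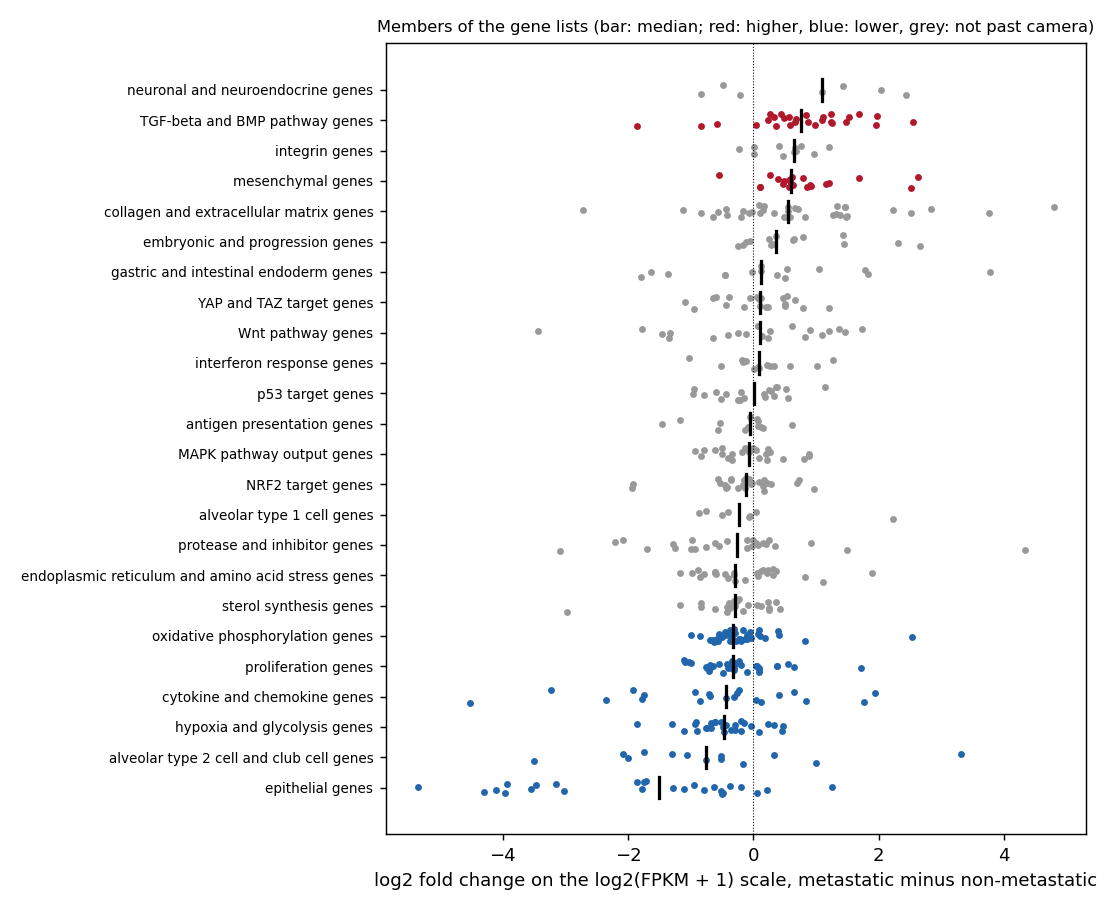
Log2 fold changes of the tested members of 24 gene lists, metastatic minus non-metastatic; each point is a gene, bars are list medians and colours mark lists past camera's test. The epithelial list has the lowest median, -1.50, and 2 lists, mesenchymal and TGF-beta and BMP pathway genes, passed with a positive direction.

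Genes tied to invasion, progression or lipid supply lay just outside the threshold in 4 lists, each with adjusted p = 0.0512. Embryonic and progression genes had a median of 0.36 (11 of 15 members positive). Among them Hmga2, an embryonic chromatin protein, averaged 182.8 ± 27.5 against 107.3 ± 37.4 FPKM (n = 2 each; log2 fold change 0.80, SE 0.30, adjusted p = 0.346) and Igf2bp3 21.8 ± 4.33 against 5.53 ± 6.61 FPKM (2.31, SE 0.92, 0.354), while H19 stood at 1.29, 25.2, 0 and 0.515 FPKM in 238N1, 482N1, 368T1 and 394T4. Cd109, a surface protein, averaged 4.03 ± 3.66 against 0.594 ± 0.296 FPKM (n = 2 each; 1.45, SE 0.65, adjusted p = 0.371). Integrin genes had a median of 0.65 (10 of 11 positive), with Itgav at 46.0 ± 27.6 against 21.0 ± 3.65 FPKM and Itgb7 at 7.23 ± 8.81 against 1.42 ± 0.859 FPKM. Protease and inhibitor genes had a median of -0.27 (17 of 26 negative): Plau, urokinase, averaged 6.99 ± 2.61 against 70.2 ± 37.6 FPKM (n = 2 each; -3.09, SE 0.48, adjusted p = 0.277), and Ctsd was listed at 0 in 394T4 with 274.4, 444.4 and 297.3 FPKM in 238N1, 482N1 and 368T1. Sterol synthesis genes had a median of -0.30 (16 of 23 negative), with Tm7sf2, a sterol reductase, at 0, 34.5, 43.4 and 48.7 FPKM. These lists passed in some fits with 1 library left out: embryonic genes without 368T1 (adjusted p = 0.00639), integrin genes without 238N1 (0.0368), protease genes without 482N1 (0.00646), and sterol synthesis genes without 238N1 (0.00403) or without 394T4 (0.0350).

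The other lists did not pass. Collagen and extracellular matrix genes had a median of 0.55 (adjusted p = 0.111); Bgn stood at 325.3, 29.2, 52.6 and 0 FPKM in 238N1, 482N1, 368T1 and 394T4, and only Lama3, listed at 0 in both metastatic lines with 5.07 and 6.17 FPKM in the others, was lower when adjusted over the list alone. Without 238N1 that list passed in the positive direction (adjusted p = 6.4e-06), but the metastatic group was then 482N1 alone, where 6 stromal markers, Acta2 among them, reached 1 FPKM. Wnt pathway genes had a median of 0.11 and a mean of -0.04 (adjusted p = 0.844), although Wnt10a and Wnt7b were lower when adjusted over the list alone. Wnt7b stood at 27.0 and 23.5 FPKM in the metastatic and 73.4 and 69.2 FPKM in the non-metastatic lines (log2 fold change -1.46, SE 0.16, adjusted p = 0.125), and Sp5, a Wnt target, averaged 0.407 ± 0.211 against 4.03 ± 2.16 FPKM (n = 2 each; -1.77, SE 0.44, 0.335).

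Signalling and stress lists showed little. MAPK pathway output genes had a median of -0.06 (adjusted p = 0.404), with Areg, an EGFR ligand, at 32.0 ± 4.36 against 62.6 ± 15.8 FPKM and Egr1 at 11.9 ± 13.3 against 3.97 ± 2.18 FPKM (n = 2 each). Without 482N1 that list passed (adjusted p = 0.0402). Genes activated by p53 had a median of 0.01 and a mean of -0.04 (adjusted p = 0.677), with Trp53inp1 at 4.22 ± 0.831 against 1.35 ± 0.301 FPKM and Cdkn1a at 9.88 ± 7.99 against 17.6 ± 6.22 FPKM. YAP and TAZ targets had a median of 0.11 (adjusted p = 0.495), with Nt5e at 11.4 ± 2.00 against 4.48 ± 1.53 FPKM and Cyr61 at 91.8 ± 55.4 against 178.1 ± 20.9 FPKM. NRF2 targets had a median of -0.12 (adjusted p = 0.224), with Aldh1a1 at 5.39 ± 2.01 against 26.2 ± 18.4 FPKM and Osgin1 at 20.1 ± 9.79 against 75.1 ± 10.9 FPKM. Endoplasmic reticulum and amino acid stress genes had a median of -0.28 (adjusted p = 0.196), with Shmt2 at 52.1 ± 12.6 against 117.3 ± 22.3 FPKM and Atf5 at 13.8, 22.7, 24.7 and 0 FPKM in 238N1, 482N1, 368T1 and 394T4. The stress list passed without 394T4 (adjusted p = 0.0350).

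Immune and lineage lists did not pass either. Interferon response genes had a median of 0.09 (adjusted p = 0.677), with Xaf1 at 1.83, 4.03, 1.43 and 0 FPKM and Cxcl10 at 1.36, 0, 1.96 and 2.32 FPKM in 238N1, 482N1, 368T1 and 394T4. Antigen presentation genes had a median of -0.06 (adjusted p = 0.404), with H2-K1 at 23.6 ± 17.3 against 47.5 ± 8.41 FPKM (n = 2 each) and Raet1d at 3.94, 2.95, 15.2 and 7.999 FPKM in 238N1, 482N1, 368T1 and 394T4. Gastric and intestinal endoderm genes had a median of 0.12 (adjusted p = 0.677), with Onecut2 at 12.8 ± 6.18 against 2.79 ± 1.12 FPKM and Hnf4a at 158.3, 137.2, 0 and 115.1 FPKM. The endoderm list passed without 482N1 (adjusted p = 0.0208). Neuronal and neuroendocrine genes had a median of 1.10 over 7 tested members (adjusted p = 0.384; percentile 99.67 of the random lists), with Gfra1 at 1.93, 8.99, 0 and 0 FPKM and Stmn2 at 0, 20.3, 0 and 0.258 FPKM. None of the 39 HOX genes averaged 1 FPKM.

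Most markers of other cell types averaged under 1 FPKM, many of them listed at 0. Of 26 leukocyte markers 24 averaged under 1 FPKM; the exceptions were Cd68, at most 2.13 FPKM, and Cd14, at 69.7, 26.5, 32.8 and 53.9 FPKM in 238N1, 482N1, 368T1 and 394T4. Of 25 fibroblast and lymph node stroma markers 23 averaged under 1 FPKM, the others being Gsn, at 84.9 to 170.3 FPKM, and Acta2, at 16.3 FPKM in 482N1 and at most 3.59 FPKM elsewhere. Of 20 endothelial markers 18 averaged under 1 FPKM; Flt1 averaged 14.1 ± 3.66 against 4.58 ± 0.790 FPKM (n = 2 each; adjusted p = 0.328; higher when adjusted over the list alone) and Eng reached 2.43 FPKM in 482N1. Among sex-specific genes, Xist stood at 27.3, 35.4, 0 and 14.0 FPKM in 238N1, 482N1, 368T1 and 394T4, and the Y-linked Eif2s3y at 5.23 FPKM in 368T1 and 0 in the others.

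The third question was how alike the 4 lines are. Spearman correlation across the 12425 genes, which are not independent replicates, was 0.878 between the metastatic lines and 0.918 between the non-metastatic lines. Between groups it was 0.910 for 238N1 and 394T4, 0.886 for 238N1 and 368T1, 0.866 for 482N1 and 394T4, and 0.836 for 482N1 and 368T1. Thus 238N1 lay closer to both lung lines than to the other metastatic line. Genes over 4-fold apart numbered 551 between the metastatic lines and 406 between the non-metastatic lines, against 416 to 788 between groups. With genes listed at 0 left out these counts were 151 and 37, against 70 to 246.

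**Figure D3:**
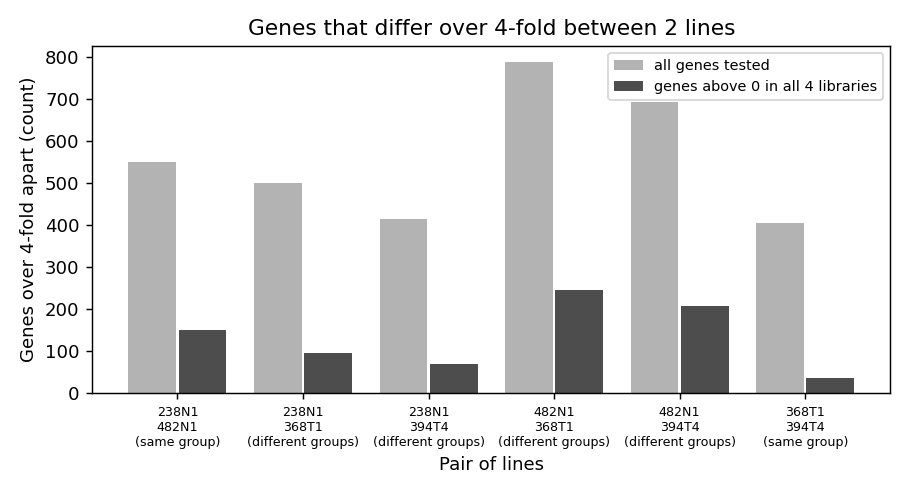
Number of genes over 4-fold apart (vertical axis, count) for each of the 6 pairs of lines, over all 12425 genes tested and over the 11454 genes above 0 in all libraries. The 3 pairs that include 482N1 have the highest counts of the latter, 151, 246 and 208.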

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

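No called gene or list changed direction under the alternatives run for single genes and lists. The 2-fold minimum, treat and rows of a symbol added up were run only for the numbers of genes called. Exact 0 as missing was not run for single named genes. Among all 85 named genes, 16 of 1291 values had the opposite sign, and among 24 lists 13 of 432, none of them called. Genes with an exact 0 left out, exact 0 as missing, protein-coding genes alone and the protein-coding sum were chosen after seeing the data. The counts of genes moved most. Against 14 higher and 6 lower, there were 1 and 1 with no filter on low values, 7 and 3 at a mean FPKM of at least 5, 31 and 13 without limma's trend, and 274 and 94 after scaling to the library sum, which put the median fold change of all genes at 0.58 (log2), against 0.045 as deposited and 0.24 with the protein-coding sum. With robust=TRUE 15 were lower. Leaving out genes with an exact 0, or treating exact 0 as missing, gave 0 higher and 6 or 4 lower, with 989 and 982 higher and 1195 and 1204 lower genes at an unadjusted p under 0.05. Each library left out in turn gave 0 and 0 (range 0 to 0), where the lone line of a group was assumed to vary like the other group. Of the 15 named genes past the test none stayed past it in those fits.

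Against 2 lists higher and 6 lower, 4 were higher with a pseudocount of 5, scaling to the library sum, median centring, genes with an exact 0 left out or 0 as missing, and 5 with quantile normalization. On the lower side 8 passed with a pseudocount of 5 or protein-coding genes alone and 4 at a mean FPKM of at least 5, and the other settings with camera's preset correlation gave 5 to 7. With each library left out the number higher ranged from 1 to 4. With an estimated correlation 0 and 0 passed, and with fry 0 and 0. For the epithelial list the adjusted p ranged from 1.0e-26 to 0.539 and was past the threshold in 16 of 18 alternatives. The robust setting does not act on camera and was not run for lists. For the genes that passed with zeros left out, the adjusted p of Sfn ranged from 6.8e-06 to 0.435, that of Wnt10a from 0.000789 to 0.490 and that of Epcam from 0.0367 to 0.398. Mean correlation within groups minus that between groups kept its sign with Pearson correlation, no filter or without genes at 0. The cause of these moves was not tested, except that a left-out library leaves 3 and a filter changes the number of genes tested. Depth limits genes of low FPKM, where 1 fragment is a visible step. No paired analysis was possible because the labels name no pairing of the lines.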

Other observations

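The tests of explanations in this part were all chosen after the results were seen, as were the genes above 0 in all 4 libraries and the matrix genes named here. Among genes above 0 in every library, Tm4sf1, a surface tetraspanin-like protein, stood at 0.421 FPKM in 238N1 and 115.6 FPKM in 482N1, Aebp1 at 2.01 and 50.4 FPKM, Wisp2 at 0.570 and 24.7 FPKM, and Fgfr1, a fibroblast growth factor receptor, at 1.86 and 43.2 FPKM. Krt7 went the other way, at 349.6 and 6.90 FPKM, as did Tns4, at 40.1 and 0.186 FPKM. Of the matrix genes, Col1a1 stood at 0.217 FPKM in 238N1 and 16.3 in 482N1, Col6a2 at 1.73 and 28.6, and Tnc at 5.41 and 92.2, while Sox2 and Vcan were at 6.18 and 21.1 FPKM in 482N1 and listed at 0 in the other 3 lines. Between the non-metastatic lines, Ccl9 stood at 1.37 FPKM in 368T1 and 589.2 in 394T4, Zfp618 at 1.79 and 61.5, and Il5ra at 1.74 and 31.8 FPKM; 238N1 held the last 2 at 72.6 and 20.8 FPKM, as 394T4 did.

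By the rule fixed for differences within a group, the largest gaps were all against a value of 0. Between 238N1 and 482N1 they were mt-Tn (29848 and 0 FPKM), CT009594.1 (5481 and 0), AC150744.1 (2106 and 0), AL772271.1 (1761 and 0), Y_RNA (1424 and 0), AC124732.1 (1110 and 0), BX571795.1 (981.6 and 0) and AL603664.2 (0 and 854.8). Between 368T1 and 394T4 they were AL772271.4 (4796 and 0 FPKM), CT009594.1 (0 and 1189), Y_RNA (1105 and 0), U5 (0 and 826.5), Fkbp1a (528.5 and 0), Hmga1 (415.2 and 0), Rpl13a (0 and 392.8) and Actn4 (381.4 and 0). Rpl13a encodes a ribosomal protein and was also listed at 0 in 482N1.

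All 20 genes past the test were listed at 0 in both lines of a group. Failed estimates in the authors' quantification would strike any pair of lines. Genes at 0 in just 2 lines, with at least 5 FPKM in both others, were counted for each pair. Pairs from different groups held 19.25 on average and pairs of the same group 30.0 (39 at 0 in 368T1 and 394T4, 21 in 238N1 and 482N1). Failure may therefore account for some such genes. Mixed pairs can also hold genes truly off in those 2 lines, so what share failure accounts for cannot be told. The share in same-group pairs, 43.8%, was above the 34.8% that the zeros per library give (exact binomial p = 0.0311, two-sided), but 39 of the 60 such genes lay in the lung pair, and genes at 0 in both metastatic lines lay within the range of the mixed pairs (15 to 25). That p takes genes as independent draws, although neighbouring genes can share their zeros, so it may be too small. Of the 15 protein-coding calls, only 6 had a gene of at least 5 FPKM within 1 kb, and for 3 of these 6 that gene had the same zeros. Yars and C77080 overlap each other, and Stat6 adjoins Nab2. The other 2 splits of the 4 lines gave 15 and 16 calls against the real 20, 1 and 1 against 6 without genes at 0, and 144 and 177 genes at an unadjusted p under 0.05 against 1787. In those splits any difference between the real groups adds to the spread within groups and lowers the counts. They are therefore not the numbers that chance alone would give.

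Lower epithelial genes in both metastatic lines were weighed against 4 explanations. A shift with expression level or scaling goes against the list's median, which lay at percentile 0 of 10000 random lists of like expression. Lists not past camera also lay at an edge, however, such as collagen and extracellular matrix genes at 100 and integrin genes at 99.96. The random lists draw genes independently, so the percentile does not set the epithelial list apart from lists whose members vary together. Failed estimates listed as 0 go against low members that were above 0 in every library, such as Epcam and Cldn4. Without genes listed at 0 the list had a camera adjusted p of 5.0e-11. That p alone says little, as camera then called 10 lists for the real groups but also 9 and 5 in the mixed splits. A smaller share of epithelial cells would lower Cdh1 along with Epcam, but their log2 fold changes lay 3.07 apart (SE 0.44), and most leukocyte, fibroblast and endothelial markers stayed under 1 FPKM. That SE takes the genes as independent, although both were measured in the same libraries, so it may be too small. Only 1 of the 3 splits, the real one, had a median change this large (1.499, against at most 0.36), but camera's p for the list was also small in a split that mixed the groups (238N1 and 368T1 against the others, unadjusted p = 0.000334), and 3 splits are too few for a share under 0.05. A loss of part of the epithelial program, with Cdh1 kept, in metastatic lines may therefore be a hypothesis for further lines, with site of origin, sex and clonal differences between 4 single lines untested.

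482N1 stood apart from the other 3 lines, with matrix genes and Bmp7 high. The median of the 25 fibroblast and lymph node stroma markers in 482N1 was 0.0249 FPKM (0.2224 FPKM over the 15 markers above 0, as values of 0 may be failed estimates). The list mixes markers of several stromal cell types, so its median could stay low with fibroblasts present. It therefore cannot decide whether stromal fibroblasts were the source. In 482N1 6 of these markers reached 1 FPKM, against 1 in 238N1, 2 in 368T1 and 2 in 394T4. Among the 6 were Mfap5 (2.89), Pdgfrb (1.22) and Thy1 (1.14). Stromal fibroblasts as part or all of the source therefore stay open. Failed estimates would leave 482N1 no further away once genes at 0 were left out, yet its closest pair still held 151 genes over 4-fold apart, against at most 96 in pairs without it. The design names no group for a single line, so what sets it apart stays open, and the mesenchymal and TGF-beta and BMP calls rest on this line.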
